A study of Mus musculus with 10 samples.

How the data were processed

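Poly(A)+ RNA and ribosome footprints of EL4 cells were used, in control cells and in cells stably expressing U2AF26 without exon 7 (dE7), which were made by electroporation of a plasmid and selection in G418, per the labels' protocols. There were 2 control and 2 dE7 RNA libraries and 3 control and 3 dE7 footprint libraries, grouped by their titles and genotype labels. The RNA titles carry B37 in all control and B36 in all dE7 libraries, which the sources used here do not explain, so in RNA the genotype cannot be separated from whatever these marks stand for. The deposited values are TPM per gene, which the authors computed over all genes of each library, per the file headers. Reads were aligned with STAR to the mouse genome, with builds mm10 and GRCm38.p6 named, per the submitters' processing notes. The program that assigned reads to genes, the gene annotation, any trimming or removal of ribosomal RNA and the handling of reads that match several genes are not given in the sources used here. Values of genes with near-identical copies elsewhere, such as ribosomal protein, histone and H2-Q genes, AF067061, BC147527 and Tmsb4x, are therefore uncertain. TPM keeps no read depth, so precision was taken from the spread between libraries.

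Each library lists 54213 genes. Biotypes and coordinates (GRCm38.p6) came from a RefSeq table, in which 37614 gene symbols matched directly, 565 by a single synonym and 16034 not at all. Of the genes, 21340 were protein coding, and 11 entries with a symbol listed more than once were left out. Tests used protein-coding genes with a mean of at least 1 TPM over the libraries of the assay (in both assays for the ratio). Values were scaled within each assay by the median of ratios over the tested genes, which gives the scaled TPM printed in the text, and taken as log2(scaled TPM + 1). Size factors were 0.98 to 1.03 in RNA and 0.72 to 1.40 in footprints.

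Genes were compared between dE7 and control with linear models and moderated t-tests with an intensity trend (limma 3.58.1, R 4.3.3), with Benjamini-Hochberg adjustment and a threshold of 0.05. RNA (2 against 2) and footprints (3 against 3) were fitted separately. The ratio of footprints to RNA was tested as the interaction of genotype and assay over all 10 libraries, with a shared spread. All p-values are two-sided. The replicate number was not in these models. In footprints, deviations from the group means correlated across genes between libraries of the same number (0.673, 0.708 and 0.297 for numbers 1, 2 and 3). Control library 1 with dE7 library 3 (0.444) and control library 3 with dE7 library 1 (0.356) lay above the number 3 pair. Deviations cancel out within a group, so a deviation shared by the libraries numbered 2 can alone give these values. A fit with the number as a block is given beside footprint and ratio results where it changes them. The labels say nothing about what the numbers mark.

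Gene lists were written before the data were examined. They cover cytosolic and mitochondrial ribosomal proteins, translation initiation and elongation factors, aminoacyl-tRNA synthetases, nuclear and mitochondrially encoded respiratory genes, the integrated stress and unfolded protein responses, chaperones, 3′ splice site factors, SR proteins and hnRNPs, mRNA decay, T cell signalling, transcription factors, activation, chemokine receptors, replication, mitosis, histones, p53 targets, apoptosis, ribosome biogenesis, glycolysis, hypoxia, cholesterol, interferon-stimulated and MHC class I genes, the proteasome, NF-kappaB, clock and immediate early genes, selenoproteins, autophagy, actin, and markers of B cells, myeloid cells and stroma. Of 38 lists, 35 with at least 5 tested members were tested with camera of limma (preset correlation 0.01), again with an estimated correlation, and with fry. Members that passed were also counted with adjustment over the list alone.

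Genes named in the text were chosen by a rule fixed before the data were examined: the 10 largest rises and the 10 largest falls of each comparison among genes past the test with groups that do not overlap and a mean of at least 5 TPM, up to 3 members past the test with the smallest adjusted p of each list, and the U2AF subunit genes. Predicted genes whose symbol is Gm with a number or ends in Rik were not named, except as the ends of stretches. List members given as values without passing, members of the chromosome 13 segment, the genes beside it, Mthfd2 and Slc3a2 in footprints, the 8 genes drawn together, the noncoding RNAs mt-Rnr1, mt-Rnr2, Malat1 and Neat1, the ratio of Il17a and values given for a gene in an assay other than the one that named it were chosen after their values were seen. So were Ighm, Trac, Trbc1 and Trbc2, list members without a protein-coding biotype. The alternatives were not run on these list members, on those noncoding RNAs, on the ratio of Il17a or on values from such other assays. Stretches of neighbouring genes shifted together were found from running medians over 15 genes beyond a log2 fold change of 0.5, with 2000 bootstrap draws for 95% intervals. The segment on chromosome 13 was also delimited from every other gene along the chromosome and tested on the genes left out.

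The tests were checked on simulated data, with 200 changed genes in each of 10 draws. A 2-fold change was found in 99.7% of genes in RNA, 36.2% in footprints and 23.6% for the ratio, and a 4-fold change in 100%, 91.0% and 88.5%. A 1.41-fold change was found in 90.4%, 0.917% and 0.607%. Of the calls, 6.40%, 6.60% and 0.846% were false, and 3, 0 and 1 of 340 unshifted lists were called. Noise was drawn independently for each gene and library, without correlation between genes or deviations shared by libraries. These shares, above all that of lists, can therefore be too low for the real data. Alternatives covered the pseudocount, the filter, the scaling, all genes of the files, the variance model, the replicate block, 1 model over all libraries and leaving out each library. Figures were drawn with matplotlib 3.10.9 (Python 3.11.15). Genes without a protein-coding biotype were left out of the main tests.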

Results

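The data describe EL4 cells, a mouse T cell lymphoma line. Control cells were compared with cells stably expressing a form of U2AF26 without exon 7, written dE7 here, which lies in the cytoplasm according to the design text. U2AF26 is encoded by U2af1l4 and is a paralog of U2AF35, encoded by U2af1, the small subunit of the factor that binds the 3′ splice site. Poly(A)+ RNA was measured in 2 control and 2 dE7 libraries. Ribosome-protected fragments, called footprints here, were measured in 3 control and 3 dE7 libraries. The RNA served to correct footprints for transcript level, so the design asks for changes in RNA, in footprints and in the ratio of footprints to RNA, the translational efficiency. All 10 libraries list 54213 genes in TPM. Such values sum to 1000000 in each library and keep no read depth, so the depth is unknown and a change shared by all genes cannot be seen.

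Protein-coding genes took 92.5% to 92.9% of the TPM in the RNA libraries and 12.7% to 19.9% in the footprint libraries. The mitochondrial methionine tRNA gene mt-Tm reached 192848 TPM in control footprint library 3, and the 5.8S ribosomal RNA gene n-R5-8s1 held 6608 to 105007 TPM in the footprint libraries. Between 10094 and 10152 protein-coding genes reached 1 TPM per RNA library, and 9138 to 9685 per footprint library. Across genes, the correlation of log2 values between replicates was 0.997 in both RNA groups. It was 0.82 to 0.97 within the footprint groups, where the libraries numbered 2 stood apart. The first principal component separated control from dE7 in RNA (88.0% of the variance), and in footprints it separated both libraries numbered 2 from the other 4 (62.9%), while the second separated control from dE7 (18.8%). The labels do not say whether replicates came from separate cultures or clones, so p-values rest on the spread between these libraries, which can be technical. That spread was moderated by a trend over all tested genes, so the size of very small p-values depends on the model.

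U2af1l4 (ENSMUSG00000078765.11, chromosome 7, 30563340 to 30565364, GRCm38.p6) was higher in the libraries labelled dE7 in both assays. Its RNA rose from 45.2 ± 6.24 to 244 ± 6.01 scaled TPM (SD, n = 2), a log2 fold change of 2.41 (SE 0.081, adjusted p = 2.69e-14). Its footprints rose from 3.32 ± 1.29 to 79.6 ± 10.9 scaled TPM (SD, n = 3), a log2 fold change of 4.25 (SE 0.24, adjusted p = 0.00214). The ratio of footprints to RNA was higher by 1.84 (SE 0.33, adjusted p = 0.0307; 1.03 with a pseudocount of 5). U2af2, which encodes the large U2AF subunit, did not pass in RNA (-0.17, adjusted p = 0.0601) or footprints (0.32, adjusted p = 0.783), and neither did U2af1 (0.12, adjusted p = 0.277, and 0.24, adjusted p = 0.849). The ratio of U2af1l4 no longer passed without control RNA library 1 (1.98, adjusted p = 0.123) or 2 (1.70, 0.193), dE7 RNA library 1 (1.87, 0.161) or 2 (1.81, 0.182), control footprint library 1 (1.76, 0.0881) or 3 (1.67, 0.0603), or dE7 footprint library 3 (1.80, 0.0789). The values sum whatever RNA matched the gene, endogenous or from the plasmid. The plasmid RNA may lack the untranslated regions of the gene, so the higher ratio cannot be read as a change in translation.

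**Figure D1:**
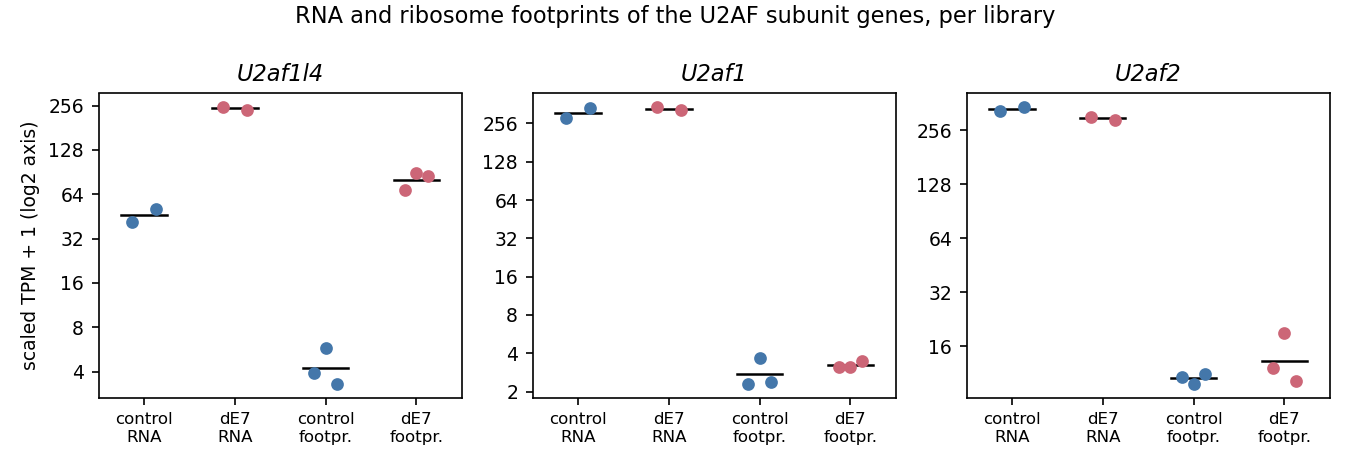
Scaled TPM + 1 (log2 axis) of the 3 U2AF subunit genes in each RNA and footprint library, with points for libraries and lines for group means of the log2 values. U2af1l4 rose in both assays (log2 fold changes 2.41 and 4.25), while U2af1 and U2af2 passed the test in neither.

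In RNA, the interleukin genes Il17a and Il17f were among the genes that rose most, and Cd2 was among those that fell most. Il17a (ENSMUSG00000025929.4, chromosome 1, 20730905 to 20734496), which encodes interleukin 17A, rose from 0.260 ± 0.128 to 236 ± 10.1 scaled TPM (SD, n = 2), a log2 fold change of 7.56 (SE 0.10, adjusted p = 1.21e-20). Its neighbour and paralog Il17f rose from 1.30 ± 0.510 to 281 ± 6.44 (6.96, SE 0.11). Il5, a cytokine gene of type 2 helper cells, rose by 4.47 (SE 0.12), and Gzmb, the gene of the cytotoxic protease granzyme B, by 3.85 (SE 0.12). Cd2, which encodes an adhesion and costimulatory receptor of T cells, fell from 88.2 ± 3.21 to 4.66 ± 1.55 (log2 fold change -4.01, SE 0.13, adjusted p = 1.06e-14). Angpt1, the gene of the vascular growth factor angiopoietin 1, was listed at 0 in both control RNA libraries and at 43.1 and 50.1 scaled TPM in the dE7 libraries. Phyh (3.47), Edil3 (3.38), D7Ertd443e (3.23) and the melanocortin receptor gene Mc5r (3.15) also rose. The other large falls were in AF067061 (-4.03), Mroh8 (-3.57), the zinc transporter gene Slc30a2 (-3.28), Cym (-2.83), the RP105 receptor gene Cd180 (-2.82), Sdsl (-2.80), the protease inhibitor gene Spint2 (-2.61), Snn (-2.38) and Igfn1 (-2.34). Fold changes of genes near 0 in a group depend on the pseudocount, and with a pseudocount of 5 they were 5.52 for Il17a, 5.51 for Il17f, 1.75 for Phyh, 2.17 for Edil3, 1.73 for D7Ertd443e, -2.65 for AF067061, -1.79 for Mroh8, -1.84 for Slc30a2, -1.55 for Sdsl, -1.60 for Spint2 and -1.24 for Igfn1. With a pseudocount of 0.1 they were 9.40 for Il17a, 5.48 for Phyh and -5.65 for Mroh8. Of 10147 protein-coding genes tested, 3163 changed in RNA, 1634 higher and 1529 lower (limma, Benjamini-Hochberg), and 367 of these changed by at least 2-fold, 212 higher and 155 lower. The balance depended on the scaling, with 1491 higher and 1696 lower on deposited TPM, 1496 and 1699 on TPM rescaled over the tested genes and 1500 and 1671 with quantile normalization. The count was 1956 without control RNA library 1, 2085 without control library 2 and 1924 without dE7 library 2. It was 486 when the spread was taken from all 10 libraries in 1 model, where Btf3, Fdps, Tmsb4x, Nars, Lars, Mars, Hspa5, Creld2, Heatr1, Polr1b, Nop16, Mki67, Aurkb, Cenpa, mt-Atp6, Adm, Mxi1 and Ero1l did not pass (adjusted p = 0.0570 to 0.738).

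Most tested SREBP targets, aminoacyl-tRNA synthetase genes and ATF4 targets rose in dE7 RNA. Of 28 genes of cholesterol biosynthesis and other targets of the SREBP factors, 17 rose, 0 fell and 11 did not pass (17 rose and 1 fell adjusted over the list alone; median log2 fold change 0.32, camera adjusted p = 3.8e-05, adjusted p = 0.616 with an estimated correlation). Hmgcr, the rate-limiting enzyme gene of the pathway, rose from 55.3 ± 2.53 to 255 ± 20.9 scaled TPM (SD, n = 2, log2 fold change 2.18) and lies in the chromosome 13 segment described with the positions of changed genes. The desaturase gene Scd1 rose by 1.02 and the farnesyl diphosphate synthase gene Fdps by 0.88. Of 22 cytosolic aminoacyl-tRNA synthetase genes, which charge tRNAs, 13 rose and 2 fell (14 and 2 adjusted over the list alone; median 0.24, camera adjusted p = 0.00128, adjusted p = 0.616 with an estimated correlation). Nars (0.60) and Lars (0.49) rose, and Mars fell (-0.57). Of 25 ATF4 targets of the integrated stress response, which slows initiation and raises amino acid supply, 14 rose and 3 fell (15 and 3 adjusted over the list alone; median 0.26, camera adjusted p = 0.00128, adjusted p = 0.616 with an estimated correlation). Chac1, a glutathione-degrading enzyme gene, rose by 1.68 (SE 0.13), the pseudokinase gene Trib3 by 1.25 (SE 0.12) and the mitochondrial folate enzyme gene Mthfd2 by 0.69 (SE 0.07).

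Most tested unfolded protein response genes and some ribosome biogenesis genes rose too. Of 20 unfolded protein response genes, 12 rose and 1 fell (13 and 1 adjusted over the list alone; median 0.23, camera adjusted p = 0.00748, adjusted p = 0.616 with an estimated correlation). The endoplasmic reticulum chaperone gene Hspa5 rose by 0.49 and Creld2 by 0.46, and Derl3, a gene of degradation from the reticulum, fell by 2.29 on the log2 scale (-0.94 and -4.06 with pseudocounts of 5 and 0.1). Of 36 ribosome biogenesis genes and MYC targets, 9 rose and 1 fell (9 and 1 adjusted over the list alone; median 0.13, camera adjusted p = 0.00402, adjusted p = 0.721 with an estimated correlation), with Heatr1 (0.56), Polr1b (0.44) and Nop16 (0.42) among those that rose. In 1 model over all 10 libraries the unfolded protein response (adjusted p = 0.103) and ribosome biogenesis (0.0811) lists did not pass, nor did they with fry (0.0571 and 0.0785).

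Most tested T cell activation and homing receptor genes rose in dE7 RNA. Of 20 tested cytokine, activation and checkpoint genes, 11 rose and 2 fell (11 and 2 adjusted over the list alone; median 0.35, camera adjusted p = 0.00187, adjusted p = 0.616 with an estimated correlation). Besides Il5 and Gzmb, the costimulatory receptor gene Tnfrsf9 rose from 3.71 ± 0.224 to 19.3 ± 1.25 scaled TPM (SD, n = 2, log2 fold change 2.11). Of 13 chemokine receptor and adhesion genes, 8 rose and 2 fell (8 and 2 adjusted over the list alone; median 0.44, camera adjusted p = 0.00134, adjusted p = 0.616 with an estimated correlation). The gut-homing integrin gene Itgb7 rose from 5.62 ± 1.34 to 32.1 ± 1.66 (2.34), the L-selectin gene Sell by 1.45 and the chemokine receptor gene Ccr4 by 0.99. Without a filter on low values the activation list did not pass (adjusted p = 0.0678).

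Some mitotic genes, and larger parts of the mitochondrially encoded and hypoxia genes, fell in dE7 RNA. Of 30 genes of G2 and mitosis, 0 rose and 9 fell (0 and 11 adjusted over the list alone; median -0.12, camera adjusted p = 0.00748, adjusted p = 0.780 with an estimated correlation), among them the proliferation marker gene Mki67 (-0.54), the kinase gene Aurkb (-0.38) and the centromeric histone gene Cenpa (-0.32). Of 13 protein genes of the mitochondrial genome, 7 fell and 2 rose (7 and 2 adjusted over the list alone; median -0.20, camera adjusted p = 0.0291, adjusted p = 0.616 with an estimated correlation). The ATP synthase subunit gene mt-Atp6 fell by 0.49 on the log2 scale. In a fit over all genes, the mitochondrial ribosomal RNAs mt-Rnr2 (0.86, adjusted p = 0.000176) and mt-Rnr1 (0.82, adjusted p = 0.000312) rose, and the nuclear noncoding RNAs Malat1 (-0.69, adjusted p = 0.000212) and Neat1 (-0.80, adjusted p = 0.00125) fell, so the RNA groups also differed in these noncoding RNAs. Of 18 hypoxia response genes, 9 fell and 1 rose (9 and 1 adjusted over the list alone; median -0.19, camera adjusted p = 0.0140, adjusted p = 0.825 with an estimated correlation). The adrenomedullin gene Adm (-0.69) and Mxi1 (-0.63) fell, and the oxidoreductase gene Ero1l rose (0.56). The mitochondrial list did not pass without dE7 RNA library 1 (adjusted p = 0.113) or 2 (0.0810), the hypoxia list did not pass without control RNA library 1 (0.140), on deposited TPM (0.0597) or on TPM rescaled over the tested genes (0.0515), and none of the 3 lists passed in 1 model over all 10 libraries (0.103, 0.154 and 0.103). With fry the mitotic (0.151) and hypoxia (0.224) lists did not pass.

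Markers of other cell types were mostly not tested, being too low or, as for the immunoglobulin gene Ighm, without a protein-coding biotype. Of 12 B cell markers only Cd22 was tested in RNA, and it fell from 13.5 ± 0.141 to 4.33 ± 0.0992 scaled TPM (SD, n = 2, log2 fold change -1.44). Ighm was abundant, with a mean of 439 TPM in RNA. In a fit over all genes it fell by 0.56 on the log2 scale (limma adjusted p = 0.000654). Of 15 myeloid markers 2 were tested, Cd68 (5.55 to 8.27, log2 fold change 0.50, adjusted p = 0.00352) and Itgam (2.01 to 1.19, -0.46, adjusted p = 0.0459). The Cd68 call was lost without control library 1 and without dE7 library 2, and the Itgam call without any of the 4 RNA libraries; over all settings the estimates were 0.33 to 0.57 and -0.71 to -0.18. Of 12 fibroblast and stromal markers 2 were tested. Pdgfra, the gene of a growth factor receptor, rose from 0.659 ± 0.152 to 9.45 ± 0.0524 (SD, n = 2, log2 fold change 2.66, and 1.35 with a pseudocount of 5), and Thy1, which T cells also express, stood at 802 and 939 (0.23, adjusted p = 0.0151), a call lost without dE7 library 1 or 2.

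Changed RNAs clustered on chromosome 13. Between Exoc3 and Ptcd2 (chromosome 13, 74169802 to 99344678, GRCm38.p6), 75 of 76 tested genes rose, with a median log2 fold change of 1.50 (95% bootstrap interval over genes 1.42 to 1.62). The other 302 tested genes of the chromosome had a median of 0.05, and the genes next to the segment, Cep72 (-0.36) and Mrps27 (0.23), lay outside the shift. The segment held 63 of the 212 genes that rose by at least 2-fold. Its members include Hmgcr, the dihydrofolate reductase gene Dhfr (1.42), the polymerase gene Polk (1.62), the lysosomal hexosaminidase gene Hexb (1.87), the ribosomal protein gene Rps23 (1.78), the translation-associated gene Btf3 (1.86), the respiratory chain genes Sdha (1.21) and Cox7c (1.74) and the peptidase gene Erap1 (1.28). In footprints the 59 tested genes of the segment had a median of 0.28 (0.22 to 0.34), against 0.21 (0.17 to 0.26) for the rest of chromosome 13 and -0.00258 for other chromosomes. The segment was delimited after the values were seen, with a window of 15 genes, and leaving out its genes left 3070 changed genes in RNA.

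**Figure D2:**
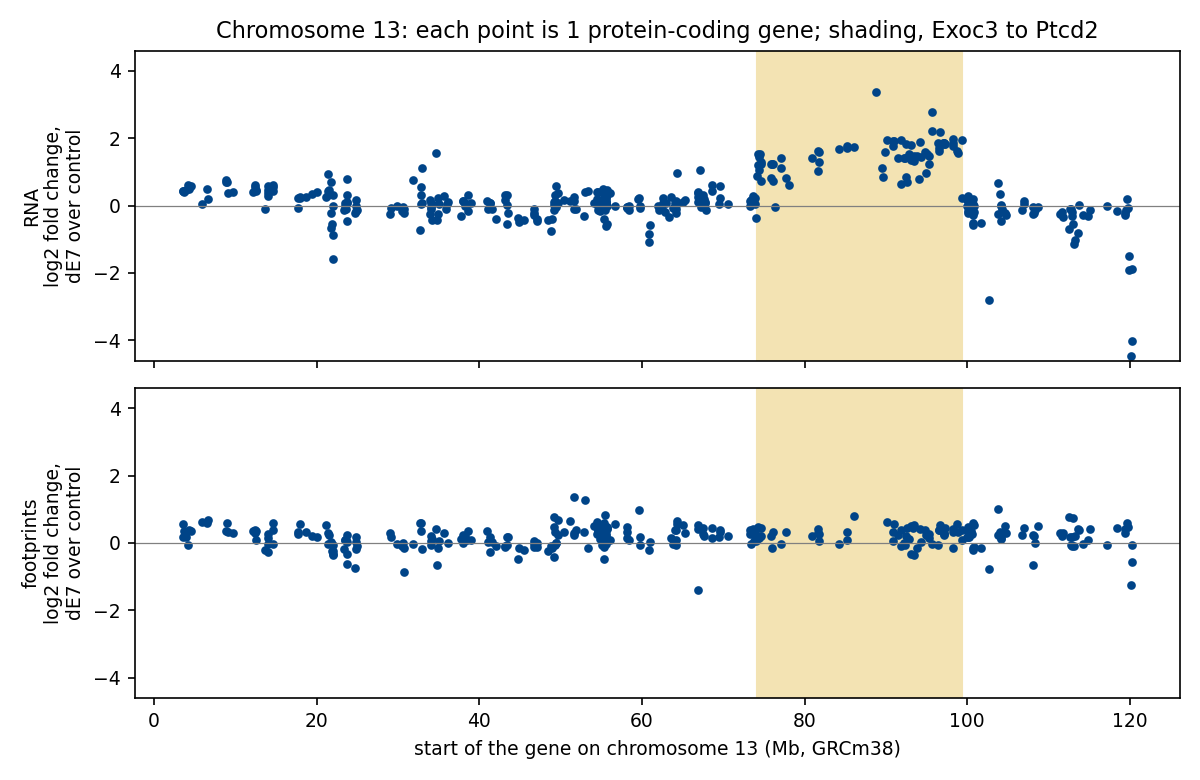
Log2 fold change (dE7 over control) of protein-coding genes along chromosome 13 (Mb, GRCm38.p6), RNA above and footprints below, with 1 point per gene and the stretch from Exoc3 to Ptcd2 shaded. The median inside the shaded stretch was 1.50 in RNA and 0.28 in footprints.

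In footprints, few genes passed the test besides U2af1l4, and those that rose most were also higher in RNA. In simulated data the footprint test found 36.2% of 2-fold changes, against 99.7% in RNA, so it can miss many changes. Nt5c2, the gene of a cytosolic nucleotidase, rose from 1.39 ± 0.325 to 28.7 ± 7.02 scaled TPM (SD, n = 3, log2 fold change 3.61, SE 0.22, adjusted p = 0.00275), and its RNA rose by 3.03. Acta2, the smooth muscle actin gene, fell from 9.96 ± 1.57 to 0.272 ± 0.0741 (log2 fold change -3.10, SE 0.16, adjusted p = 0.00214), and Il18r1, an interleukin 18 receptor gene, from 10.3 ± 0.960 to 0.391 ± 0.0198 (-3.02, SE 0.14, adjusted p = 0.00180). The mitochondrial import gene Timm10 rose by 4.01 (SE 0.36), the ubiquitin ligase gene Rnf128 by 3.31 (SE 0.27) and the matricellular protein gene Ccn4 by 2.49 (SE 0.17). Tmsb4x, the gene of the actin-sequestering peptide thymosin β4, fell from 169 ± 13.1 to 26.5 ± 7.95 (-2.67, SE 0.25), Rab11fip4 fell by 2.40 on the log2 scale, and the LIM protein gene Crip1 fell from 39.7 ± 2.72 to 9.99 ± 1.42 (-1.89, SE 0.15). Of 9598 genes tested, 21 changed, 12 higher and 9 lower (limma, adjusted p), and 829 had an unadjusted p under 0.05 against 479.9 by chance. The 2 groups of 3 did not overlap for 16.5% of genes, where chance gives 10% if the libraries are exchangeable. The deviation shared by the libraries numbered 2 goes against that, so 10% is only a rough guide. With the replicate number as a block, 53 genes changed, including these 21. The count fell to 10, 11 and 4 without control footprint libraries 1, 2 and 3, and to 8 and 4 without dE7 libraries 1 and 3. Without control library 3 or dE7 library 3 the calls of Timm10 (adjusted p = 0.0725 and 0.0901), Rnf128 (0.0725 and 0.0749), Ccn4 (0.0640 and 0.0607), Rab11fip4 (0.0640 and 0.0607), Crip1 (0.0725 and 0.0620) and Tmsb4x (0.109 and 0.0620) were lost, and those of Nt5c2, Acta2, Il18r1 and U2af1l4 were kept under every setting. The Tmsb4x and Crip1 calls were also lost without control library 1 (0.115 and 0.0693), control library 2 (0.0872 and 0.0614) or dE7 library 1 (0.0812 and 0.0582), and that of Timm10 without dE7 library 1 (0.0698). On TPM rescaled over the tested genes the calls of Timm10 (0.0600), Ccn4 (0.0756), Tmsb4x (0.0920), Rab11fip4 (0.0502) and Crip1 (0.0600) were lost as well. With a pseudocount of 5 the fold changes were 2.38 for Nt5c2, 1.94 for Rnf128, -1.50 for Acta2, -1.51 for Il18r1 and -1.59 for Rab11fip4, and with 0.1 that of Acta2 was -4.77.

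As groups, stress response and clock genes had higher footprints in dE7 cells and replication genes had lower ones, without single members past the test over all genes. The 24 ATF4 targets of the integrated stress response had a median log2 fold change of 0.42 (0 passed, 4 rose adjusted over the list alone; camera adjusted p = 3.2e-06, adjusted p = 0.396 with an estimated correlation), with Mthfd2 at 0.68, Slc3a2 at 0.74 and Chac1 at 1.05. The 14 circadian clock genes had a median of 0.32 (0 passed, 3 rose adjusted over the list alone; camera adjusted p = 8.7e-04, adjusted p = 0.396 with an estimated correlation), with the nuclear receptor gene Nr1d1 at 1.24 and the repressor gene Nfil3 at 1.27. The 33 DNA replication genes had a median of -0.23 (0 passed, 0 adjusted over the list alone; camera adjusted p = 3.5e-04, adjusted p = 0.541 with an estimated correlation), with the cyclin E2 gene Ccne2 at -2.05 and the primase gene Prim1 at -0.82. Among genes with a mean of at least 5 TPM the clock list did not pass (adjusted p = 0.0502). In dE7 library 2, which stood apart, these lists lay further in the direction of the call than in dE7 libraries 1 and 3. The median differences were 0.14 for stress response, 0.30 for clock and -0.28 for replication genes. The other lists called in footprints deviated likewise there. The stress response, clock and replication calls were kept without that library. With fry none of these lists passed (adjusted p = 0.0937, 0.141 and 0.289).

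Other lists passed in footprints with adjusted p nearer the threshold. The 22 T cell transcription factor genes had a median of 0.18 (0 passed, 0 adjusted over the list alone; camera adjusted p = 0.0156, adjusted p = 0.396 with an estimated correlation), with Gata3 at 0.83 and Tcf7 at 0.79. The 19 genes of MHC class I antigen processing had a median of -0.20 (0 passed, 0 adjusted over the list alone; camera adjusted p = 0.0156, adjusted p = 0.396 with an estimated correlation), with Psmb9 at -0.64. The 21 interferon-stimulated genes had a median of -0.30 (0 passed, 0 adjusted over the list alone; camera adjusted p = 0.0263, adjusted p = 0.682 with an estimated correlation), with Stat2 at -0.52. The 22 immediate early genes had a median of 0.36 (0 passed, 2 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.0263, adjusted p = 0.690 with an estimated correlation), with Jun at 0.98 and Dusp6 at -1.13. Without control footprint library 1 the adjusted p rose to 0.0517 for the transcription factor and MHC lists, 0.102 for the interferon list and 0.119 for the immediate early list. Without control library 3 it was 0.0580 for the MHC, 0.0666 for the interferon and 0.0581 for the immediate early list, and without dE7 library 2 it was 0.614 for the interferon and 0.893 for the immediate early list. Among genes with a mean of at least 5 TPM it was 0.0502 for the transcription factor list and 0.129 for the interferon and immediate early lists. With the replicate number as a block, 2 more lists passed, mitochondrially encoded proteins with lower footprints (median -0.23, adjusted p = 0.0234) and glycolysis with higher ones (median 0.18, adjusted p = 0.0252); without the block, their adjusted p was 0.667 and 0.396 with an estimated correlation. Leaving out libraries also added lists: dE7 library 2 the aminoacyl-tRNA synthetases (0.00484), cholesterol (0.0139), glycolysis (0.0177), chaperones, T cell activation and p53 targets (0.0431 each), dE7 library 1 the mitotic genes (0.00257), control library 1 the synthetases (0.0439), and control library 2 (0.0107) or dE7 library 3 (0.0281) the mitochondrially encoded proteins; no list passed with an estimated correlation when all libraries were kept. Other-cell markers did not pass in footprints: of 3 B cell markers, Cd79b stood at -0.98 (adjusted p = 0.364, lower when adjusted over the list alone), Cd22 at 0.02 and Ebf1 at 0.21, and 1 myeloid and 1 stromal marker stood at -0.51 and 0.10.

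**Figure D3:**
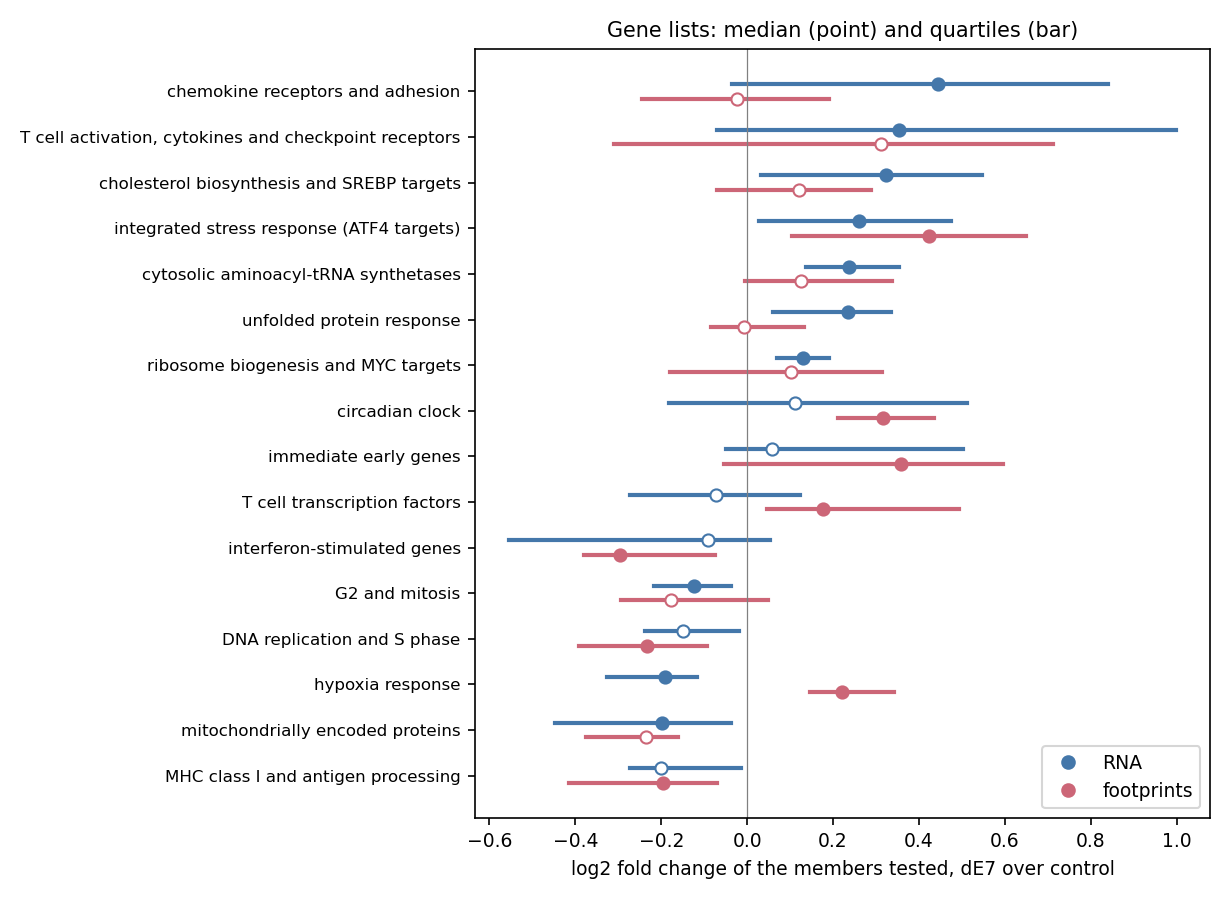
Median (point) and quartiles (bar) of the log2 fold change, dE7 over control, of tested members of the gene lists called in RNA or footprints, with filled points where camera called the list and open points where it did not. Cholesterol genes had a median of 0.32 in RNA, and hypoxia genes lay at -0.19 in RNA and 0.22 in footprints.

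The ratio of footprints to RNA changed mostly in genes whose RNA had changed without a matching change in footprints. Cd2 had a ratio higher by 3.78 on the log2 scale (SE 0.35, adjusted p = 0.00158). Its RNA fell to 4.66 scaled TPM, while its footprints stood at 34.4 ± 9.52 in control and 28.9 ± 5.55 in dE7 cells (SD, n = 3). Sdsl (2.68, SE 0.25) and Snn (2.38, SE 0.26) behaved alike, with Snn footprints at 48.6 ± 8.10 and 48.8 ± 8.57. The ratio fell for Gzmb (-3.28, SE 0.34, adjusted p = 0.00205), whose footprint change was 0.57 (adjusted p = 0.605), for Itgb7 (-2.55, SE 0.25), whose footprints stood at 61.7 ± 5.25 and 53.3 ± 8.51, and for the interferon-stimulated gene Usp18 (-4.14, SE 0.23, adjusted p = 8.5e-05), whose RNA rose by 3.32. Il17a, with 3.22 to 5.99 scaled TPM in every footprint library, had a ratio change of -7.30 (adjusted p = 1.93e-06). For Acta2 (-2.45, SE 0.19) and Crip1 (-1.82, SE 0.20) it was the footprints that fell further than the RNA (-0.66 and -0.07). The ratio of Timm10 rose by 2.62, as footprints rose further than RNA (1.39). Cd180 (2.04), BC147527 (1.82) and the transcription factor gene Spib (1.77) rose, and the phosphatase gene Dusp6 (-2.57), Pglyrp2 (-2.31), the tubulin gene Tuba8 and Sema4f (-1.78) fell.

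**Figure D4:**
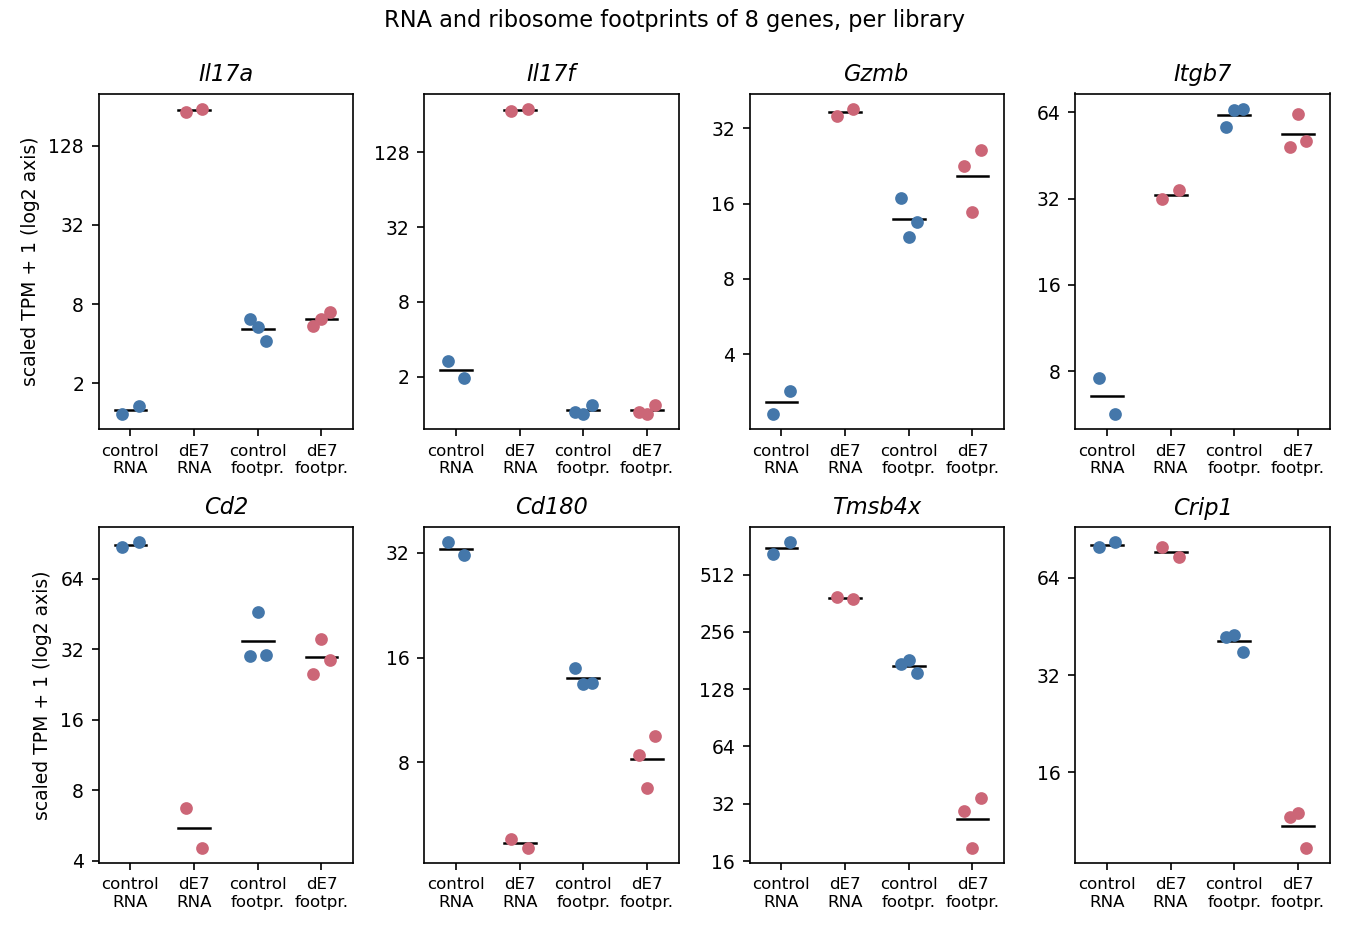
Scaled TPM + 1 (log2 axis) of 8 genes in each RNA and footprint library, with points for libraries and lines for group means of the log2 values. Il17a, Il17f, Gzmb and Itgb7 rose and Cd2 and Cd180 fell in RNA with no footprint change past the test (Il17f was too low to test there), while Tmsb4x and Crip1 fell in footprints.

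Of 9163 genes tested for the ratio, 126 changed, 52 higher and 74 lower (limma interaction of genotype and assay over all 10 libraries, adjusted p), and 966 had an unadjusted p under 0.05 against 458.15 by chance. RNA had changed in the opposite direction for 48 of the 52 and 67 of the 74, and footprints had changed for 12 of the 126. The RNA values enter both the ratio and the RNA comparison, so these counts share their libraries. Of the 74 lower genes, 27 lay in the chromosome 13 segment, among them Hmgcr (-1.65). With the replicate number as a block, 191 genes changed, 120 of them among the 126. On deposited TPM 49 changed, 33 higher and 16 lower, that is 67.3% higher against 41.3%. The count was 37 and 39 without control RNA libraries 1 and 2, 37 and 38 without dE7 RNA libraries 1 and 2, 80 and 74 without control footprint libraries 1 and 3, and 259 without dE7 footprint library 2. Of the genes named here, the calls of Cd2, Sdsl, Snn, Gzmb, Itgb7, Usp18 and Acta2 were kept under every setting, and that of Timm10 was lost without any of the 4 RNA libraries (adjusted p = 0.156 to 0.183), control footprint library 3 (0.0560) or dE7 footprint libraries 1 (0.0625) and 3 (0.0756), and with pseudocounts of 0.1 (0.102) and 0.5 (0.0562). The Pglyrp2 call was lost without control RNA library 1 (adjusted p = 0.0676) or 2 (0.0624) or dE7 RNA library 2 (0.0753), and that of Spib without control RNA library 1 (0.0551) or dE7 RNA library 2 (0.0566). Other scalings ended further calls: TPM rescaled over the tested genes those of Cd180, BC147527, Dusp6, Hmgcr, Spib, Pglyrp2, Timm10 and Il5, and deposited TPM those of Crip1, Tuba8, Sema4f, Hmgcr and Spib. With a pseudocount of 5 the ratio changes were 1.46 for Sdsl, 1.62 for Timm10, -2.18 for Gzmb and -0.88 for Acta2, and over all settings that of Acta2 was -4.10 to -0.88.

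As groups, hypoxia genes had a higher ratio of footprints to RNA in dE7 cells and homing receptor genes a lower one. The calls came from camera with its preset correlation, and neither list passed with fry (adjusted p = 0.127 and 0.0727). The RNA of each list, which enters the ratio, had shifted the other way, so a change in translation cannot be concluded. The 18 hypoxia response genes had ratio changes of 0.04 to 1.05, with a median of 0.39 (0 passed, 0 adjusted over the list alone; camera adjusted p = 0.00319, adjusted p = 0.611 with an estimated correlation). Their RNA median was -0.19 and their footprint median 0.22 (camera adjusted p = 0.0226, adjusted p = 0.396 with an estimated correlation). Adm stood at 1.05 and Mxi1 at 0.94. The footprint call was lost on deposited TPM (0.0674), with quantile normalization (0.0897) and without control library 1 (0.0590) or dE7 library 2 (0.248). Of 12 chemokine receptor and adhesion genes, 2 fell and 10 did not pass (1 rose and 3 fell adjusted over the list alone; median -0.59, camera adjusted p = 0.0155, adjusted p = 0.611 with an estimated correlation), Itgb7 and Sell (-1.42). The call of the list was lost without dE7 footprint library 2 (0.0777). Of 16 T cell activation genes, 4 fell and 1 rose (6 and 4 adjusted over the list alone; median -0.28), and the list did not pass (camera adjusted p = 0.138) except on deposited TPM (2.5e-05); it was 0.611 with an estimated correlation on the scaled values. Il5 fell by 3.32 on the log2 scale. The Sell call was lost without control RNA library 1 (0.234) or 2 (0.190), dE7 RNA library 1 (0.187) or 2 (0.237), control footprint library 3 (0.0746) or dE7 footprint library 3 (0.0905). It was also lost with pseudocounts of 0.1 (0.113) and 0.5 (0.0712), without a filter (0.0544), on deposited (0.807) and rescaled TPM (0.440), over all genes (0.0560) and without the segment (0.0504). Among markers of other cell types, Cd22 had a ratio change of 1.46 (adjusted p = 0.0313), 1 myeloid marker stood at -1.01 and 1 stromal marker at -0.13, neither past the test. The Cd22 call was lost without any 1 of the 4 RNA libraries, control footprint libraries 1 and 2 or dE7 footprint libraries 1 and 3. It was also lost on deposited and rescaled TPM, with quantile normalization and with a mean of at least 5 TPM. The Cd22 estimates were 1.00 to 1.64 over all settings.

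Changes in RNA and in footprints, which share no library, were weakly related across genes. Over 9163 genes, which are not independent replicates, Pearson's correlation of the log2 fold changes was 0.276 and Spearman's 0.146. The 1453 genes that rose in RNA had a median of 0.39 in RNA and 0.06 in footprints, and the 1406 that fell had -0.37 and -0.06. The 151 that rose at least 2-fold in RNA had 1.46 and 0.33, and the 107 that fell at least 2-fold had -1.46 and -0.46. Of the 10 genes higher in footprints and tested in both assays, 8 were higher in RNA, among them U2af1l4, Nt5c2, Rnf128 and Ccn4, against 1.59 for independent lists, and of the 8 lower in footprints 6 were lower in RNA against 1.23.

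**Figure D5:**
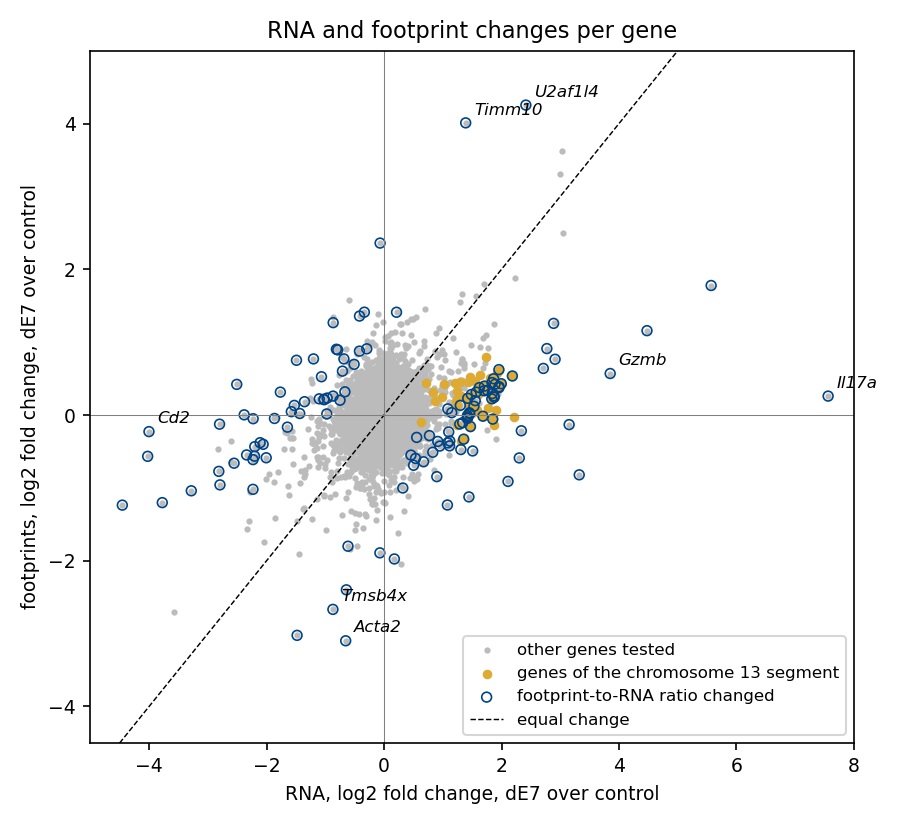
Log2 fold change (dE7 over control) in RNA and in footprints, with 1 point per gene tested in both, genes of the chromosome 13 segment in yellow, genes with a changed footprint-to-RNA ratio circled and a dashed line of equal change. Most circled genes lie along the RNA axis, such as Il17a (7.56 in RNA, 0.26 in footprints), and few along the footprint axis, such as Acta2 (-0.66 and -3.10).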

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

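The tests of extra copies, of scaling, of footprint noise, of cells that differed and of a shared preparation were chosen after the results were seen, and the others before.

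On chromosome 13, the difference between dE7 and control libraries was unlike in the 2 assays for 27 genes between Exoc3 and Ptcd2. All had a lower ratio of footprints to RNA by the interaction test. The lowest segment median over 4 scalings was 1.48. Each scaling acts on a whole library and can hardly move 1 segment against other genes. The outcome was therefore largely fixed in advance, and no conclusion is drawn from it. Extra copies of the segment in the dE7 cells used for RNA cannot be told apart from other causes. With the segment delimited anew from every other gene, from Fastkd3 to Tnpo1, 84.1% of 44 genes left out inside it had an RNA log2 fold change above 0.5, against 6.21% of 145 elsewhere on the chromosome, where at least 90% had been asked for. This stretch starts at 68582167, before Exoc3 at 74169802, so it can take in genes outside the segment. Between Exoc3 and Ptcd2, 98.7% of 76 genes lay above 0.5, but these genes had served to delimit it. DNA was not analysed here, a regional change in transcription was not tested, and the unexplained marks in the RNA titles go with the genotype.

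Over all genes, the difference between dE7 and control libraries was unlike in RNA and footprints for 126. In the segment, which holds 27 of them, the upper bound of the interval of the footprint median was 0.336, far under the RNA median of 1.50. The interval was drawn over genes, so it argues against footprint noise of single genes there. It does not measure noise that genes share within a library, and it does not cover the genes outside the segment. Cells that differed in genome or state between the RNA and footprint libraries, such as different clones or passages, cannot be told apart from translational offset of the RNA changes. The segment's offset against the rest of chromosome 13 in the ratio of footprints to RNA was -1.71 in dE7 and -0.32 in control, which restates the pattern and would follow from both. The rest of chromosome 13 had higher footprints (median 0.21) with little RNA change (0.05), which an offset of RNA changes would not give. Those genes lie outside the segment, so this does not decide the matter for the 126. The largest chromosome medians in RNA, 0.179 on chromosome 15 and -0.139 on chromosome 5, had footprint medians of -0.0513 and 0.00227. RNA shifts of whole chromosomes were thus not seen in footprints either. Both explanations can give RNA shifts without footprint shifts, so these medians do not decide between them. Only 6 noncoding genes, which are not translated, had a 4-fold RNA change and a mean of at least 1 TPM in both assays. Their median change in the RNA direction in the footprint libraries was 1.18 (-0.21 to 2.33). Genes under 1 TPM in the footprint libraries were left out, which can tilt this median toward changes that were kept. The ratio changes of Cd2, Gzmb and Itgb7 may thus reflect different cells as well as translation.

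The 2 footprint libraries numbered 2 stood apart from the other 4 in both genotypes. They listed the fewest genes above 0, 21247 in control and 18839 in dE7, against 24744 to 25949 in the other 4, so they may hold fewer reads. Fewer reads as the whole cause are argued against, since the deviations of the 2 libraries correlated at 0.888 among genes with a mean of at least 50 scaled TPM. A preparation shared by libraries of the same number cannot be told apart from other causes, since 4 of 6 libraries correlated best with the library of their own number. No biological explanation was tested, since the labels name no factor that the numbers mark.

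The 6 footprint libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 21 genes changed in footprints, as did 1 of 10 splits counting itself, and the highest other gave 0. For the ratio, with the RNA libraries kept, 4 of 20 assignments gave at least the 126 genes of the real one, so chance was not excluded. The highest other, 395, was the mirror of the real assignment, which sets the footprint labels against those of the RNA. Among assignments that part all 3 same-numbered pairs, the others gave 45 to 93 genes, and those that keep a pair together gave 43 to 226. With RNA changed in 3163 genes, assignments without a footprint effect also give ratio changes, a structure of the design.

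Among genes without a protein-coding biotype, which the main tests of the report left out, 140 had higher and 185 had lower RNA in dE7 cells, of 2934 tested together with all other genes. In the footprint libraries 3 of 3831 such genes changed, all lower.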

How the results depend on the processing

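The block in the footprint libraries only, the removal of both footprint libraries numbered 2 and the removal of the chromosome 13 segment were chosen after seeing the data, and the other alternatives before. U2af1l4 kept its rise in RNA and footprints under every alternative. Its limma adjusted p in RNA ran from 0.00165 without a filter to 7.7e-176 with the replicate block, so its size depends on the model. Of the genes past the test that the naming rule picked, no call reversed, and 53 of 124 in RNA, 3 of 13 in footprints and 7 of 30 for the ratio were kept under every alternative, U2af1l4 not counted and not all of them named in the text. Where no reason is given, the cause was not tested.

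RNA changes numbered 3163, against 1918 without a filter, 486 in 1 model over all 10 libraries, whose spread includes the footprints, and 1924 to 2191 with 1 library left out, where fewer libraries remain and a lone library was assumed to vary like the others. The RNA libraries share only a number (correlation of deviations -0.0794), and with that number as a block 3108 genes and 4 of the 10 lists passed; the aminoacyl-tRNA synthetase (adjusted p = 0.0736), mitotic (0.113), ribosome biogenesis (0.152), mitochondrially encoded (0.255), unfolded protein response (0.261) and hypoxia (0.113) lists did not.

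Footprint changes numbered 21, against 13 with a pseudocount of 0.1, 13 with a mean of at least 5 TPM, 36 on deposited TPM, 8 on TPM rescaled over the tested genes, 53 with the replicate block, 184 in 1 model over all 10 libraries, 79 without both libraries numbered 2 and 4 to 18 with 1 library left out. Ratio changes numbered 126, against 290 with a pseudocount of 5, 237 without a filter, 55 with a mean of at least 5 TPM, 49 on deposited TPM, 22 on rescaled TPM, 191 with the replicate block, 271 with 1 weight per assay, 292 from footprints of each library over mean RNA, which leaves out the spread of RNA, 360 with the block in the footprint libraries only, 610 without both libraries numbered 2 and 37 to 259 with 1 library left out. On deposited TPM the median of all genes was 0.15 in footprints and 0.16 in the ratio, against 0.00378 and 0.00594. The ratio change of U2af1l4 was 1.67 to 2.10 with 1 library left out, 1.03 and 2.16 with pseudocounts of 5 and 0.1, and passed with the block (adjusted p = 0.0118). The block ended the ratio call of Bcl2 and changed no other named or list call in footprints and the ratio than those given in the report.

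The correlation of RNA and footprint changes was 0.276, against 0.238 with a mean of at least 5 TPM, 0.304 with a pseudocount of 0.1, 0.322 without both libraries numbered 2 and 0.225 to 0.287 with 1 library left out. No list passed with an estimated correlation, and with fry none of the lists called in footprints or the ratio did, nor did the unfolded protein response (adjusted p = 0.0571), mitotic (0.151), ribosome biogenesis (0.0785) and hypoxia (0.224) lists in RNA. In footprints 8 further lists passed without both libraries numbered 2 (adjusted p = 0.0164 to 0.0479), 5 in 1 model over all 10 libraries (0.0345 to 0.0461), 3 with a mean of at least 5 TPM (0.0254 each), 3 without a filter (0.0113 to 0.0418), 2 on deposited (0.00183 and 0.0147) and 2 on rescaled TPM (0.0318 and 0.0424), and 2 with fry (0.0343 and 0.0491). Leaving out both libraries numbered 2 also ended footprint calls, those of the hypoxia (camera adjusted p = 0.193), interferon-stimulated (0.172) and immediate early (0.445) lists. It ended the ratio call of the chemokine receptor and adhesion list as well (0.0730). In the ratio T cell activation passed on deposited TPM (2.5e-05), and cholesterol (0.0441) and the unfolded protein response (0.0346) with a mean of at least 5 TPM. Without the segment 3070 RNA and 89 ratio changes were left. Depth is unknown and its limit was not measured.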

Other observations

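The stretches of shifted genes were looked for after the data were seen. Besides the chromosome 13 segment, 5 stretches of neighbouring genes shifted together in dE7 RNA (GRCm38.p6). On the X chromosome, 35 genes from Ubqln2 to Gm15246 (153498232 to 169370141) had a median log2 fold change of -0.61, 18 genes from Cstf2 to Trap1a (134059176 to 139338169) -0.57, and 13 genes from Rnf128 to Apex2 (139563340 to 150588206) 0.66. On chromosome 10, 33 genes from Gas2l3 to 4930430F08Rik (89408822 to 100589390) had 0.58, and on chromosome 13, 14 genes from Akr1c13 to Lgals8 (4191168 to 12464977) 0.54. Rnf128 rose by 2.99 in RNA and Tmsb4x, also on the X chromosome, fell by 0.87 on the log2 scale.

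The lists not passed in RNA held changed members in both directions, except the chaperones; counts adjusted over the list alone follow in parentheses. Of 82 cytosolic ribosomal protein genes 1 rose and 3 fell (1 and 3), among them Rps23 (1.78, in the segment) and Rpl36a (-0.58), and of 78 mitochondrial ones 8 rose and 6 fell (5 and 6), among them Mrpl32 (0.61) and Mrpl54 (-0.42). Of 43 initiation factor genes 12 rose and 5 fell (12 and 5), with the translational repressor gene Eif4ebp1 at 0.65 and Eif1ax at -0.50, and of 18 elongation and termination genes 4 rose and 2 fell (4 and 2), with the kinase gene Eef2k at -0.56. Of 75 nuclear genes of oxidative phosphorylation 5 rose and 13 fell (4 and 13), with Ndufa12 at 0.55. Of 19 chaperone genes 2 rose and 0 fell (2 and 0), with Cct2 at 0.48. Of 18 genes of 3′ splice site recognition 5 rose and 4 fell (5 and 5), with Phf5a at 0.48 and Zrsr2 at -0.62. Of 35 SR protein and hnRNP genes 4 rose and 3 fell (3 and 3), with Hnrnph2 at -0.42, and of 23 mRNA decay genes 1 rose and 4 fell (0 and 4), with Pan2 at -0.59 and Dcp1b at -0.69 (-0.43 with a pseudocount of 5).

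Immune lists were mixed in RNA as well. Of 22 T cell receptor signalling genes 9 rose and 8 fell (9 and 9), with Ptprc at 0.65 and Cd2 at -4.01, and of 20 T cell transcription factor genes 4 rose and 8 fell (5 and 9), with Gata3 at 1.02 and Ikzf3 at 0.93. The receptor chain genes Trac, Trbc1 and Trbc2 were left out of the count for their biotype. In a fit over all genes they rose by 0.31, 0.65 and 0.89 (limma adjusted p = 0.0104, 0.00147 and 0.000725). Of 21 interferon-stimulated genes 2 rose and 7 fell (2 and 8), with Gbp2 at -1.96 and Oas3 at -1.24 (-1.23 and -0.80 with a pseudocount of 5; camera adjusted p = 0.115), and of 19 MHC class I genes 2 rose and 10 fell (2 and 11), with Psmb9 at -0.38 (camera adjusted p = 0.0609, and 0.0128 without the segment, which holds Erap1; adjusted p = 0.825 with an estimated correlation over all genes). Of 18 NF-kappaB genes 2 rose and 4 fell (2 and 4), with Nfkbia at -0.41. Of 19 immediate early genes 7 rose and 2 fell (8 and 2), with the phosphatase genes Dusp6 at 1.44 and Dusp4 at 1.04 (camera adjusted p = 0.0608).

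Of 34 replication genes 4 rose and 13 fell (4 and 13), with Mcm3 at 0.67 and Ccne1 at -0.47 (camera adjusted p = 0.0510, and 0.0133 without the segment; adjusted p = 0.825 with an estimated correlation over all genes). Of 18 p53 targets 4 rose and 4 fell (4 and 4), with Sesn1 at -0.57, of 19 apoptosis genes 3 rose and 4 fell (4 and 5), with Bmf at -1.12 and Bcl2 at 0.55, and of 10 histone genes 2 rose and 3 fell (2 and 3), with Hist1h1c at 0.78 and Hist1h2bj at -1.57. Of 18 glycolysis genes 4 rose and 1 fell (4 and 1), with the lactate transporter gene Slc16a3 at 0.78, and of 31 proteasome genes 2 rose and 1 fell (1 and 0), with Psma2 at 0.43. Of 16 clock genes 6 rose and 2 fell (6 and 3), with Hlf at 1.86 and Cry1 at 0.62. Of 22 selenoprotein and antioxidant genes 7 rose and 3 fell (7 and 4), with Gsr at 0.51, of 24 autophagy and lysosome genes 6 rose and 1 fell (5 and 1), with Ctsd at 0.80 and Tfeb at -0.82, and of 31 actin genes 5 rose and 7 fell (5 and 7), with Tmsb4x at -0.87 and Flna at 0.47. With a pseudocount of 5 the changes of the less abundant Bmf (-0.54), Hist1h2bj (-0.79), Hist1h1c (0.48) and Hlf (0.82) were smaller, and with 0.1 that of Hlf was 2.79.

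Several of these lists passed in RNA under other settings, none of them with an estimated correlation over all libraries. Without control RNA library 1 the cytosolic ribosomal proteins (adjusted p = 5.3e-06), oxidative phosphorylation (4.2e-04), replication and MHC class I (0.0115 each) and immediate early genes (0.0338) passed, without control library 2 the chaperones (0.0187) and the proteasome (0.0438), and without dE7 library 2 replication (0.0222), interferon-stimulated (0.0413) and immediate early genes (0.0324). With quantile normalization oxidative phosphorylation (0.00920), replication (0.0114) and MHC class I (0.0131) passed, and without a filter replication (0.0125), MHC class I (0.0266) and autophagy (0.0280). Replication passed with pseudocounts of 0.1 (0.0461) and 0.5 (0.0498), and narrowly with 5. The immediate early genes passed with a mean of at least 5 TPM (0.0225), on rescaled TPM (0.0478) and without the segment (0.0400), and with fry autophagy (0.00713) and clock genes (0.0399) did.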
